A study of Drosophila melanogaster with 2 samples.

How the data were processed

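Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after laying, from a transgenic line in which CG6813 carries GFP at its C-terminus. Per the labels, the fusion protein was precipitated with an antibody against GFP and chromatin was fragmented by sonication to 200 to 800 bp. The samples form 1 group of 2 biological replicates, which the labels number 2 and 3. Replicate 1 was not analysed here. No control library was used here.

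The authors deposited a region list for each replicate, a list for both replicates pooled, and a thresholded list, each on dm6 and on dm3. Per the file listing deposited with the samples, the per-replicate and pooled lists held peaks and background passed to an irreproducible discovery rate (IDR) step, the thresholded list was the optimal set of that step, and regions were called against a control. The aligner, the caller and the IDR cutoff are not given in the sources used here. Each region carried a signal value that the authors deposited as the peak caller gave it, and its normalization is not given in the sources used here. Each region also carried a deposited −log10 q-value, which reached its highest value, 3.70, in 50.1% of the thresholded dm6 peaks and was therefore not used for ranking. Read depth is unknown, since the lists hold no counts. Signal values were used to describe, rank and filter peaks within a list, and the ratio between replicates describes the deposited values only.

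The thresholded dm6 list held 5012 peaks. All 5012 were rows of the pooled list of 30000 regions and were its 5012 strongest regions by signal. The thresholded dm3 list held 3963 peaks, likewise the strongest of its pooled list. In dm6, 6 peaks repeated the coordinates of another peak with a different summit and were kept. All coordinates below are dm6, 1-based, and no coordinate was converted between builds. Gene models came from the BDGP6.54 annotation (18277 genes, 13968 of them protein-coding, on chromosome arms X, 2L, 2R, 3L, 3R, 4 and Y) and sequence from the matching RefSeq assembly. Every arm's last region ended before the end of the arm's sequence. Transposable elements were left out of the genes and of the transcription start sites (TSSs).

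A summit within 500 bp of a TSS was called a promoter summit and any other a distal one. A gene was called bound when a thresholded summit lay within 500 bp of any of its TSSs. Regions of different lists were matched when their summits lay within 200 bp. Replicate overlap was tested with 1000 permutations of the ranks in the replicate 3 list (one-sided). Promoter share was tested against 1000 random placements on the same arm and, with Fisher's exact test, against pooled regions farther than 500 bp from every thresholded summit. Differences in median log2 signal and correlations across peaks used permutation tests with 100000 resamples. Arms were tested with exact binomial tests against their share of protein-coding TSSs. The 24 gene lists were tested with Fisher's exact test against all other protein-coding genes. The 16 consensus sequences and all 8192 7-mers, joined with their reverse complements, were compared between the 100 bp on each side of a summit and an equal window centred 500 bp away on a side drawn at random, with an exact McNemar test. The sides were drawn again with another random seed after values of the first draw had been seen, for a reason unrelated to them, and the first draw is kept as an alternative. Divergent genes, with a TSS of another gene on the opposite strand within 500 bp upstream, were counted among bound and unbound protein-coding genes. The odds ratio was set against 200 draws of 5012 pooled regions, and promoter summits, each counted once by its nearest protein-coding TSS, were compared between thresholded peaks and other pooled regions with Fisher's exact test. The consensus sequences were also compared between bound and unbound promoters, within 150 bp of the TSS, with Fisher's exact test. Tests were two-sided unless stated, and Benjamini-Hochberg adjustment was applied within each family at 0.05. Intervals of shares are exact 95% binomial intervals and cover counting error only. Peaks, genes and sequence windows are not independent replicates of the experiment, so these p-values do not measure the spread between embryo collections.

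The gene lists, consensus sequences, main tests, most alternatives and the rule for naming genes were fixed before the data were examined. The draws and the count of each summit once were added after, as were the alternatives named as such with the results. The rule named the 20 strongest thresholded peaks with a region in both replicates, each by the gene of its nearest TSS, the 4 members with the highest promoter signal of each list that passed, CG6813 itself, each consensus sequence that passed and the 10 7-mers with the lowest p. Genes named outside this rule were chosen after their values were seen, as were the annotation classes and the transposable element count. List members were matched by symbol or synonym, and 1 member of the testis list was not matched. Alternatives fixed beforehand covered each replicate alone, a stricter threshold, other distances and windows, other backgrounds and the dm3 lists.

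On simulated data the 7-mer test recovered 20 of 20 7-mers written into 5% of 5012 windows and made 0 calls between flanks with nothing written in. Both sides there were flanks, alike in composition, so this does not cover summits and flanks that differ in GC. With an odds ratio of 3, the list test recovered 85.5% of lists of 80 genes and 21.5% of lists of 20 genes, and it called 0.295% of unchanged lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.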

Results

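The binding sites of CG6813, a zinc finger protein with an N-terminal zinc finger-associated domain (ZAD), were mapped in whole Drosophila embryos by ChIP-seq of a GFP-tagged protein. There was 1 group with 2 biological replicates, so the comparisons are between the replicates and between the bound sites and the rest of the genome. Each replicate list held 30000 regions, and the authors' thresholded list held 5012 peaks, the strongest of the pooled list by signal. The depth of the libraries is unknown. Signal values are the authors', per peak.

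The replicates placed their strongest regions at many of the same sites. The strongest peak of both lay 27 bp upstream of Ugalt, which encodes a UDP-galactose transporter, with a signal of 2776 in replicate 2 and 963.0 in replicate 3. The peak in an intron of CG11050 ranked 2 in replicate 2 and 4 in replicate 3, and that near cbt, which encodes a zinc finger transcription factor, ranked 3 in both. Of the 5012 strongest regions of replicate 2, 3547 (70.8%) had one of the 5012 strongest of replicate 3 within 200 bp. Permuted ranks gave 17.5% on average and at most 18.9% (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). The thresholded peaks were the 5012 strongest regions of the list pooled from both replicates. They were thus picked by pooled signal, and values across them are no separate measure of agreement. Of these peaks 4927 (98.3%) had a region in both replicates, and across them log2 signal had a Pearson r of 0.757 and a Spearman rho of 0.651 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The replicates differed in scale, with a median ratio of 2.19 (replicate 2 over replicate 3, interquartile range 1.72 to 2.78). Of the thresholded peaks, 91.0% were among the 5012 strongest regions of replicate 2 and 78.8% among those of replicate 3. The strongest regions of neither replicate included 55 of the peaks.

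**Figure D1:**
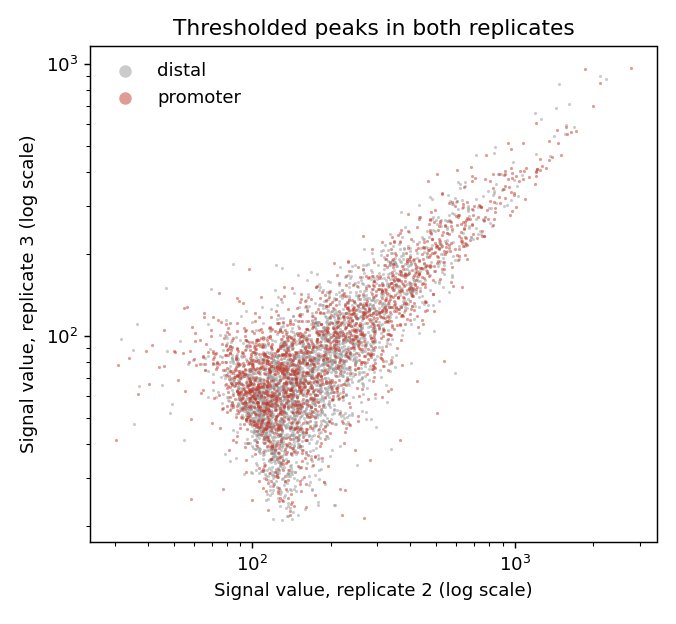
Signal value of each of the 4927 thresholded peaks with a region in both replicates, replicate 2 on the x axis and replicate 3 on the y axis, both log scales without unit. Promoter and distal peaks lie along the same diagonal, and the spread is wider among weak peaks.

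CG6813 peaks lay at promoters and in introns and were rare in coding exons. Of the 5012 summits, 2033 (40.6%, 95% interval 39.2 to 41.9%) were promoter summits, against 13.6% of randomly placed summits (range 12.1 to 15.4%, permutation p = 0.002, the smallest that 1000 placements can give). Beyond the promoters, 2113 summits (42.2%) lay in introns, against 39.4% of random ones, and 695 (13.9%) were intergenic, against 27.2%. Only 22 summits (0.439%) lay in coding exons, against 13.7% of random ones, and 51 (1.02%) in 3′ UTRs, against 4.41% (adjusted permutation p = 0.00266 for each of these classes). The 39 summits in 5′ UTRs outside promoters matched the random share (0.778 against 0.776%). Annotated transposable elements held 9 summits (0.180%), against 5.79% of random ones. Random placements covered every assembled base, and whether regions could be called equally in each class was not checked. A shortfall in a class therefore need not mean less binding there. Among pooled regions away from thresholded peaks, 22.4% of 24053 lay at promoters (odds ratio 2.36, Fisher's exact p = 2.02e-146). Promoter summits lay a median of 100 bp upstream of the TSS, and 1498 (73.7%) were upstream of it. Median signal was 233.5 at promoter and 222.0 at distal peaks, a log2 difference of 0.07 (permutation p = 0.0011), and with promoters defined by 200 bp the difference was 0.03 (permutation p = 0.233). It was 0.15 without replicate 3, 0.17 among peaks strong in both replicates and 0.25 among the 2506 strongest (permutation p = 1e-05 for each).

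**Figure D2:**
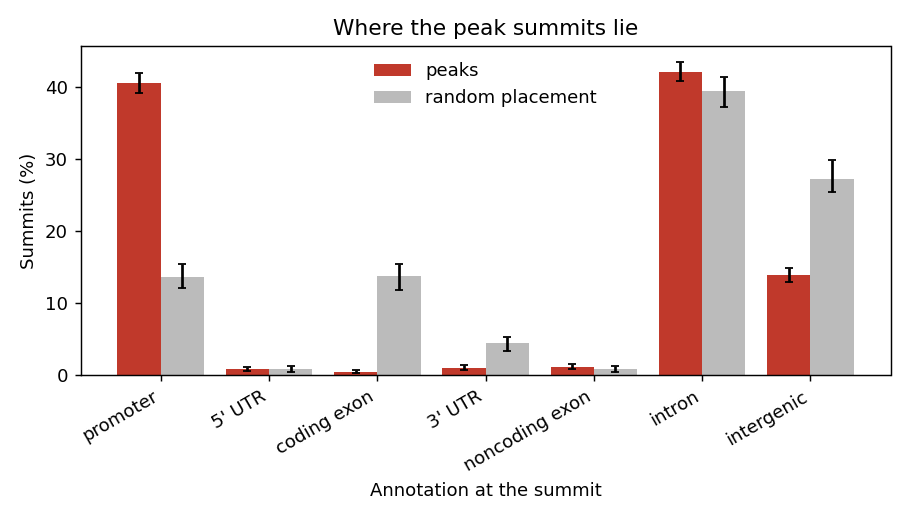
Percentage of the 5012 peak summits in each annotation class (red, bars with exact 95% binomial intervals) and of randomly placed summits (grey, mean with the lowest and highest of 1000 placements). Promoters held 40.6% of summits against 13.6% at random, and coding exons 0.439% against 13.7%.

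The 20 strongest peaks found in both replicates were headed by those at Ugalt, CG11050, cbt and px. Among them, 11 lay at promoters, 8 in introns and 1 in a noncoding exon, and none ranked below 20 in replicate 2 or below 30 in replicate 3. Promoter peaks lay at Ugalt (X, 2703698 to 2704056, pooled signal 3734), px (2R, 22514109 to 22514477, 2954), lncRNA:CR31840 (2L, 14023897 to 14024317, 2789) and CG14100 (3L, 19590451 to 19590777, 2701). Further promoter peaks were those of ph-p, a Polycomb group gene, with a signal of 2234 and a summit 470 bp upstream of its nearest TSS, and of PNPase (2196), CG1888 (2131), CenG1A (2124), Tina-1 (2029), Chro (1967) and mRpS10, a mitochondrial ribosomal protein gene (1959). Intronic peaks stood in CG11050 (2L, 6612434 to 6612899, 3118), in Lk6, which encodes a protein kinase (3R, 11760890 to 11761235, 2340), in sbb (2R, 18336882 to 18337352, 2329), 20116 bp from its nearest TSS, and in Trl, which encodes the GAGA factor (3L, 14759326 to 14759713, 2256). The peak nearest to cbt (2L, 480902 to 481278, 3051) lay 1366 bp upstream of its TSS, inside an intron of ush. Introns of CG32772, cno and Tlk held peaks with signals of 2169, 2112 and 2098. The peak nearest to lncRNA:CR44619 (2020) lay in a noncoding exon of lncRNA:Vinr.

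The CG6813 gene itself (FBgn0037923, 3R, 11625051 to 11626638, minus strand) had no peak nearby. The nearest thresholded summit and the nearest pooled one were 9117 bp from its TSS, and the nearest were 9115 bp away in replicate 2 and 9154 bp away in replicate 3.

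Peaks were spread unevenly over the chromosome arms, with few on chromosome 4. Chromosome 4 held 10 peaks, against 36.9 expected from its share of protein-coding TSSs (ratio 0.271, adjusted exact binomial p = 2.36e-06). Y held 0 peaks against 5.98 expected (adjusted exact p = 0.0105), but it also held 0 of the 30000 pooled regions, so this says nothing about binding there. Arm 3L held 1095 peaks, 1.13 times the expected number (adjusted exact p = 2.92e-05), and 2R held 927, 0.905 times (adjusted exact p = 0.00131). X, 2L and 3R held 856, 941 and 1183 peaks, with ratios of 1.01, 0.998 and 1.00. Against the share of assembled sequence 2L gained a call (ratio 1.09, adjusted exact p = 0.00634). The 2R call was lost against the share of assembled sequence (adjusted exact p = 0.940), without replicate 2 (0.0908) and among peaks strong in both replicates (0.123). Among the 2506 strongest peaks it was the only 1 of the 4 arm calls that passed. Chromosome 4 still lay below its expected number among them (adjusted exact p = 0.0889). Observed over expected minus 1 was -0.512 there and -0.729 for all peaks.

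The genes of cytoplasmic ribosomal proteins were bound far more often than other genes. Of 86 such genes, 67 (77.9%, interval 67.7 to 86.1%) had a promoter peak, against 14.4% of the other protein-coding genes (odds ratio 21.0, adjusted Fisher's exact p = 6.37e-38). The strongest were at RpL7 (2L, TSS 10201100, summit 47 bp upstream, signal 1458), RpS27 (3R, TSS 25247514, 1215), RpL14 (3L, TSS 8601006, 1074) and RpL24 (2L, TSS 13395131, 1006). Genes of architectural proteins, which bind insulators and organise chromosome domains, were bound in 7 of 15 cases (odds ratio 5.06, adjusted exact p = 0.0112), among them Chro (signal 1967), Cp190 (734.3), Dref (654.2) and Trl (424.8). The Dref peak is the one at the RpL13 promoter, and without genes bound only by a peak of a ribosomal protein gene, an alternative added after the data were seen, 6 of 14 were bound (adjusted exact p = 0.0344). That alternative leaves out bound genes only, so it could only lower the share. Of 22 genes of the Notch pathway and the Enhancer of split complex, 9 were bound (odds ratio 4.01, adjusted exact p = 0.0105), with E(spl)m7-HLH (442.8), E(spl)m3-HLH (393.2), E(spl)mdelta-HLH (343.1) and neur (266.8) the strongest. In all, 2063 protein-coding genes (14.8%) were bound, and 7 of 24 lists passed, the histone list below among them. Against only those genes with a pooled region at the promoter, ribosomal protein genes were bound in 83.8% of cases against 35.0% (adjusted exact p = 1.55e-17), while neither the architectural list (70.0 against 35.7%, odds ratio 4.21) nor the Notch list (64.3 against 35.6%, 3.25) passed (adjusted exact p = 0.163 for each). These odds ratios were little below those against all genes, on 10 and 14 genes. The Notch call was also lost with promoters of 200 bp (adjusted exact p = 0.176) and among the 2506 strongest peaks (0.244).

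Several gene groups were bound less often than other genes. None of 185 chemoreceptor genes (upper limit 1.97%, adjusted Fisher's exact p = 2.50e-12) and none of 96 cuticle protein genes (3.77%, adjusted exact p = 1.93e-06) had a promoter peak, though 15 genes of each list had a pooled region there. None of 111 replication-dependent histone genes had a peak (adjusted exact p = 3.20e-07), but 0 had a pooled region either, so this says nothing about binding at them. Of 301 snoRNA and snRNA genes, 21 (6.98%) were bound (odds ratio 0.433, adjusted exact p = 0.000232), with the highest signals at snoRNA:Psi28S-2949 and snoRNA:Or-aca5 (1075, a shared peak), snoRNA:U49:66Da (1074) and snoRNA:Or-CD11a (712.5). This call was lost with promoters of 1000 bp (adjusted exact p = 0.873) and against genes with a pooled region (adjusted exact p = 0.817). Of the 21 genes, 8 had only a peak that a ribosomal protein promoter shares, snoRNA:U49:66Da (RpL14) and snoRNA:Or-CD11a among them. Without genes bound only by such a peak, 13 of 293 were bound (odds ratio 0.272, adjusted Fisher's exact p = 2.74e-07). Only bound genes could be left out this way, so the share could only fall. The lower odds ratio is therefore no further evidence of less binding. The peak of snoRNA:Psi28S-2949 and snoRNA:Or-aca5 lay 48 bp upstream of Uhg4, an ncRNA gene whose span holds both. Annotated 5′ ends served as TSSs, and whether each snoRNA gene has a promoter of its own was not checked.

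The remaining 17 lists did not pass. Mitochondrial ribosomal protein genes were bound in 9 of 73 cases, oxidative phosphorylation genes in 7 of 78 and proteasome genes in 1 of 32. Polycomb and trithorax group genes were bound in 7 of 21 (adjusted exact p = 0.0795), including ph-p, brm (signal 793.1) and E(z) (631.7). The 26 ZAD zinc finger genes, the family of CG6813, had 4 bound members, CG4820, M1BP, pad and Sry-delta, and the CG4820 peak is the one at the RpS25 promoter. Bound members numbered 8 of 31 for replication and cell cycle, 4 of 17 for aminoacyl-tRNA synthetases, 5 of 23 for segmentation, 5 of 17 for muscle and mesoderm, 4 of 14 for heat shock and 3 of 9 for clock genes. There were 35 of 290 tRNA genes bound, and among genes with a pooled region they were bound less often (19.6 against 35.7%, adjusted Fisher's exact p = 5.32e-05). The number of TSSs per gene, each a chance to be called bound, was not matched in the list tests. Neighbouring genes can also share a peak. Bound were 1 of 8 Hox genes (Dfd), 1 of 18 neural genes (elav, signal 1453), 1 of 22 piRNA pathway genes (cuff), 0 of 8 dosage compensation genes and 0 of 13 testis-expressed genes, of which 0 had a pooled region. Lists of about 20 genes had little power to pass at an odds ratio of 3, the only one simulated.

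**Figure D3:**
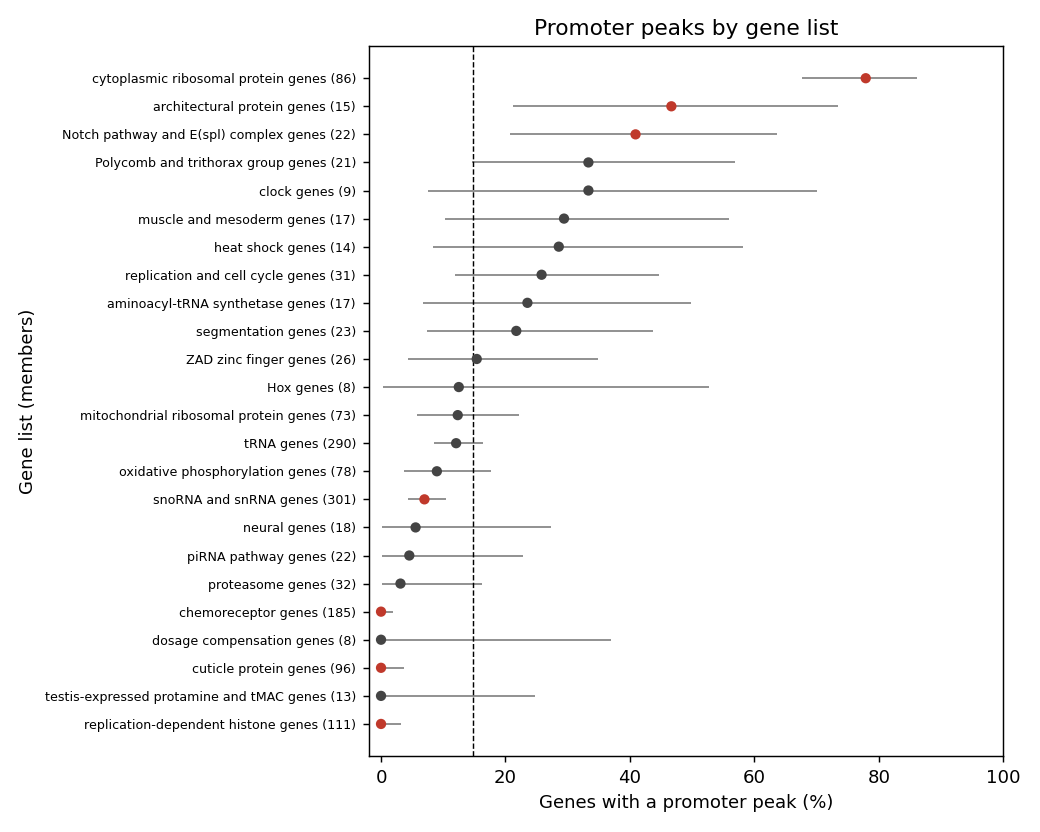
Percentage of each list's genes with a promoter peak (x axis) for the 24 lists, number of members in brackets, with exact 95% binomial intervals. Red points passed the adjusted test, the histone list with no pooled region among them, and the dashed line is the share of all protein-coding genes, 14.8%.

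Bound genes more often carried GAGA repeats and more often stood at divergent promoters. Of the 2063 bound protein-coding genes, 905 (43.9%) had a TSS of another gene on the opposite strand within 500 bp upstream, against 3230 of 11905 unbound genes (27.1%, odds ratio 2.10). A summit between a divergent pair can count for both genes, so genes are not independent here. The odds ratio was 1.34 with TSSs within 200 bp, a setting for which no draws were made. At 500 bp, as many regions drawn from the whole pooled list, thresholded peaks included, gave 1.41 on average (1.22 to 1.71 over 200 draws). That value is to be set against 2.10. With each promoter summit counted once by its nearest protein-coding TSS, a test added, like these draws, after the data were seen, 622 of 1858 thresholded summits (33.5%) and 1164 of 4697 other pooled ones (24.8%) lay at divergent genes (odds ratio 1.53, Fisher's exact p = 2.06e-12). The GAGA sequence, read by GAGA factor and CLAMP, stood within 150 bp of the TSS in 13.2% of bound and 4.61% of unbound genes (adjusted exact p = 2.26e-41). The CA repeat was found in 8.87 against 4.11% (adjusted exact p = 6.55e-17), the E-box of Ohler motif 5 in 23.6 against 17.3% (1.53e-10) and Ohler motif 7 in 11.1 against 8.34% (0.000160). ZIPIC (3.05 against 1.86%, adjusted exact p = 0.00184) and CTCF sequences (1.45 against 0.790%, 0.00980) were also more frequent. The TATA box was less frequent at bound promoters (6.20 against 10.1%, adjusted exact p = 2.29e-08), as was the Pho sequence (6.64 against 8.58%, 0.00647). The TSS was the one nearest a summit in bound genes but the most 5′ one in unbound genes. Part of these differences may come from that choice, which was not tested. Of these 8 calls, only those of GAGA, the CA repeat and the E-box passed when unbound genes were restricted to those with a pooled region, with log2 odds falling from 1.65 to 0.95, from 1.19 to 0.52 and from 0.56 to 0.39. The CTCF call was also lost without replicate 3 (adjusted exact p = 0.242), within 100 bp of the TSS (0.675), among the 2506 strongest peaks (0.250) and among peaks strong in both replicates (0.168). The Pho call was lost in these last sets too (0.222 and 0.0589), and that of motif 7 among peaks strong in both replicates (0.0589).

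At the summits themselves, some sequences of insulator proteins and core promoters were more frequent than in the flanks, though each was rare. The CTCF sequence stood in 74 of 5012 summit windows (1.48%) and 26 flanks (0.519%, adjusted exact McNemar p = 8.89e-06). DRE, read by Dref and BEAF-32, stood in 1.70 against 0.599% (2.86e-06), ZIPIC in 0.878 against 0.299% (0.000616) and su(Hw) in 0.698 against 0.299% (0.0151). Of the core promoter sequences, Ohler motif 7 was found in 3.25 against 1.68% of windows (adjusted exact p = 2.86e-06), TATA in 3.89 against 2.71% (0.00403), motif 1 in 0.698 against 0.279% (0.0101) and motif 6 in 0.439 against 0.140% (0.0163). The other 8 of the 16 sequences did not pass, among them the initiator (18.6 against 17.6%, adjusted exact p = 0.277), the E-box of motif 5 (9.14 against 8.78%, 0.601), GAGA (6.28 against 5.37%, 0.0843) and Pho (4.21 against 5.05%, 0.0843). The flank sides were drawn again after first values had been seen, and with the first draw Pho passed as less frequent (0.0380). With the flank on the other side Pho (0.00170) and GAGA, as more frequent (0.0387), passed, so both calls turn on the side drawn. Against pooled regions with no thresholded peak nearby, matched on promoter or distal position, 1 of these 8 calls, CTCF, passed. With GC matched too, an alternative added after the data were seen, CTCF and ZIPIC passed. Their log2 odds were then 1.12 and 1.27 (adjusted Fisher's exact p = 0.0011 and 0.00502). Among the 2506 strongest peaks the calls of su(Hw), motif 1 and motif 6 were lost (adjusted exact p = 0.243, 0.245 and 0.211), and among peaks strong in both replicates those of su(Hw) and motif 6 (0.0752 and 0.0736). Within 50 bp su(Hw), motif 6 and TATA were lost (0.158, 0.0567 and 0.0591), and motif 6 without replicate 3 (0.0571). The log2 odds of su(Hw), motif 6 and TATA were 0.97, 1.95 and 0.51 within 50 bp, against 1.20, 1.59 and 0.54 within 100 bp. No relation to peak signal was called for any of the 8, the lowest adjusted permutation p being 0.479 (ZIPIC, median signal 269.9 in 44 peaks with it and 225.7 without). With 22 to 195 peaks holding each sequence, small relations could have been missed.

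Short AT-rich sequences and a group of sequences built on CAGTG were more frequent at summits than in the flanks. Sequences of the CAGTG group can overlap within a longer sequence, so they need not be separate elements. TACACTG, the reverse complement of CAGTGTA, shares CACTG with CACTGAG, and CACAGTG shares ACAGTG with ACAGTGG. CAGTGTA stood in 333 summit windows (6.64%) and 82 flanks (1.64%, adjusted exact McNemar p = 3.55e-35), CACTGAG in 5.77 against 1.54%, ACAGTGG in 7.96 against 2.99% and CACAGTG in 6.78 against 2.35%. The AT-rich ones were AAATATT (21.9 against 11.2%, adjusted exact p = 1.48e-43), ATATTTA (20.8 against 10.9%), GTAAATA (12.5 against 5.61%), ATATTTG (14.7 against 7.26%), AAATATA (19.9 against 12.1%) and AATATTA (12.7 against 6.46%). CAGTGTA was present in 7.75% of distal summits (flanks 1.95%) and 5.02% of promoter summits (flanks 1.18%). Its log2 odds fell from 2.09 against flanks to 0.97 against matched pooled regions and 0.72 with GC matched, and those of CACTGAG from 1.96 to 0.91 and 0.68, all past the threshold. In all, 801 7-mers were more frequent at summits and 1211 less frequent, out of 8192. Summit windows held less GC than flanks, 38.7 ± 8.79% against 43.5 ± 9.60% at promoters and 37.7 ± 7.33% against 41.3 ± 8.21% at distal peaks (SD over 2033 and 2979 windows). Against pooled regions matched on GC, an alternative added after the data were seen, 124 7-mers passed, and AAATATA, AATATTA and ATATTTA did not (adjusted exact p = 0.940, 0.153 and 0.162). Matched on position alone, 1926 7-mers passed. The log2 odds of AAATATT were 1.16 against flanks, 0.91 against regions matched on position and 0.30 with GC matched too. Those of ATATTTG were 1.14, 0.87 and 0.45, and those of GTAAATA 1.26, 0.96 and 0.63. Much of the AT-rich difference thus went with base composition, and part with the change of background. AT-rich 7-mers are themselves part of a window's low GC. Matching on GC therefore cannot tell composition from a preference for these sequences. With replicate 3 alone, without replicate 2, 819 7-mers passed.

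**Figure D4:**
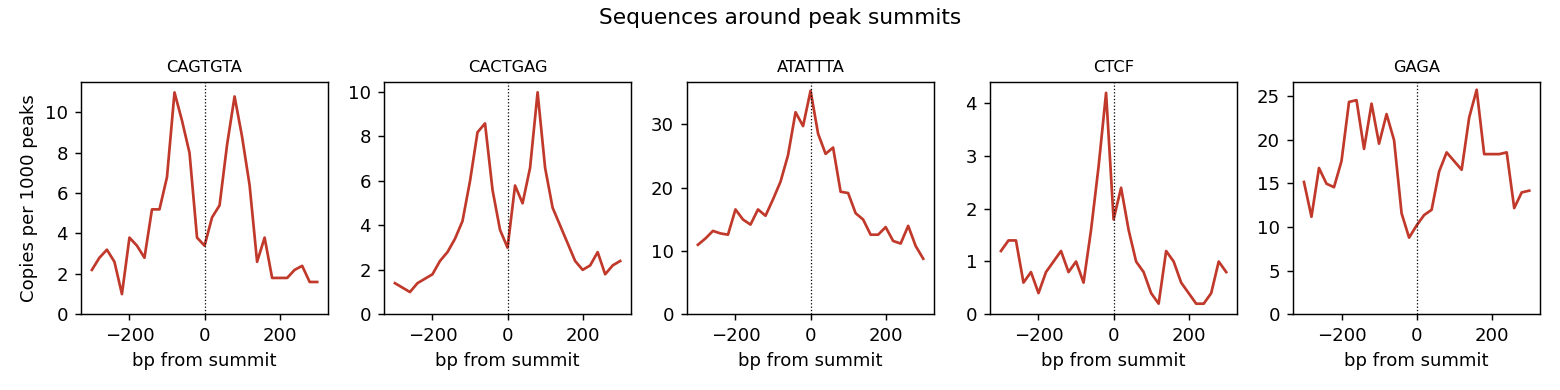
Copies of 5 sequences per 1000 thresholded peaks (y axis) in 20 bp bins around the summit (x axis, bp). CAGTGTA and CACTGAG are most frequent on both sides of the summit, ATATTTA and the CTCF consensus at or next to it, and the GAGA repeat is least frequent near it.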

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

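The pooled dm3 list, which the comparisons of peak positions do not use, held 17 regions on unplaced or heterochromatic sequences outside the 7 chromosome arms. A fixed limit of 3 was set for flagging, and the count was not tested.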

How the results depend on the processing

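The alternatives using peaks among the strongest of both replicates, GC-matched regions, the flank on the other side or as first drawn, genes bound only by a ribosomal gene's peak left out, or summits counted once were chosen after the data were seen. Of 76 values of main results under alternatives, 64 kept their direction and side of the threshold, or, for counts, stayed within 1.5 times, whether or not the same members passed. Replicate overlap ranged from 65.0 to 75.0% and the promoter share's odds ratio from 2.12 to 3.03. The promoter to distal difference in log2 signal missed the threshold at 200 bp (0.0281). Chromosome arm calls fell from 4 to 1 among the 2506 strongest peaks, where fewer peaks were tested, and to 2 among the 3555 peaks strong in both replicates. Against genes with a pooled region, where 22 of the 24 lists had such members, 4 lists passed, 3 of the 7 and tRNA genes. The odds ratio of divergent promoters ranged from 1.34 to 2.30. Summit motif calls fell from 8 to 5 within 50 bp. Against matched pooled regions 2 passed, 1 of them among the 8, and with GC matched too 4, 2 of them among the 8. With the flank on the other side 10 passed and with the first draw 9, these 8 among them, so sequences near the threshold depend on the side drawn. Sizes moved as well. With the flank on the other side the log2 odds of su(Hw) rose from 1.20 to 2.70 and of ZIPIC from 1.53 to 2.24. Promoter motif calls fell from 8 to 5 among peaks strong in both replicates and to 4, 3 of them among the 8, against unbound genes with a pooled region. The 2012 7-mer calls became 819 without replicate 2 and 2444 without replicate 3, 1278 among peaks strong in both replicates and 124 with GC matched. Against pooled regions matched on position 1926 passed and with the flank on the other side 1834, in each case 1309 of them among the 2012. Directions turned, none past the threshold, for 2R against assembled sequence (observed over expected minus 1, 0.0027), for snoRNA and snRNA genes at 1000 bp (log2 odds 0.0674) and against genes with a pooled region (0.208), for motif 1 against matched regions (-0.0797), and with GC matched for TATA (-0.0454) and AAATATA (-0.0448). The cause was not tested except where stated. Of 275 values of single lists, arms and sequences, 225 kept their call, 44 lost it and 6 turned. Neither replicate could be left out of the replicate comparisons. No paired analysis was possible because there is a single group. Read depth, which limits weak peaks, is unknown.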

Other observations

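Some strong promoter peaks lay at genes of lists that did not pass, chosen here after their values were seen. Hsp83, which encodes a heat shock chaperone, had a promoter peak of signal 1800 (rank 26), Hsp27 903.3 and Hsp26 372.5. The muscle and heart gene tin had a peak of 715.6, 190 bp upstream of its TSS, and the neural gene elav a peak of 1453. Among mitochondrial ribosomal protein genes, mRpS23, mRpS10 and mRpL41 had signals of 2124, 1959 and 1833, that of mRpS23 being the peak at the CenG1A promoter.

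The tests in this part were chosen after the patterns were seen, except the orientation of CACTGAG, whose test was set before its result was known. CAGTGTA and CACTGAG lay beside the summit: of copies within 100 bp, 24.8% (371 copies) and 26.1% (314 copies) were within 40 bp, where 40.3% of positions lie, and in each replicate alone both shares were also lower (adjusted exact p at most 0.0160). Among thresholded peaks ACAGTGG (23.8%) and CACAGTG (25.7%) also had lower shares (adjusted exact binomial p at most 3.45e-09), as had the GAGA repeat (26.9%). The 772 GAGA copies outnumber the 315 summit windows that hold the repeat, so its copies were not independent. The GAGA share was 28.9% in replicate 2 and 36.6% in replicate 3. The pattern was thus not particular to CAGTGTA and CACTGAG. These sequences can overlap within a longer one, so their values need not be independent. How often their copies overlapped was not counted. Displaced summits as the whole cause are argued against by the CTCF consensus, with 67.0% of its 88 copies within 40 bp. AT-rich summits are argued against for CAGTGTA, at percentile 0 of 965 7-mers with as many G and C bases, but stay open for CACTGAG, at percentile 3.19, since its interval (21.3 to 31.3%) spans their 5th percentile (27.0%). That the whole interval must lie below was required only after both shares were seen. The bound set first, on the shares alone, was met by both (26.1% for CACTGAG). Of 232 CACTGAG copies more than 40 bp away, 191 (82.3%, interval 76.8 to 87.0%) read towards the summit (exact binomial p = 2.47e-24). A sequence oriented towards a bound site, the hypothesis set beforehand, would give this. The test counted any departure from an even split, so a majority reading away would have passed too. Copies at promoter and distal peaks were not separated. No other biological explanation was tested.

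The peaks at cytoplasmic ribosomal protein promoters may reflect the factor or the promoters' activity. Calling of regions at these promoters whatever their strength is argued against as the whole cause, since among genes with a pooled region the odds ratio was still 9.56. Signal at any highly transcribed gene stays open. Oxidative phosphorylation genes had an odds ratio of 0.567 against all other protein-coding genes, but 1.15 among genes with a pooled region (7 of 18 bound). No transcript level was analysed here to show how strongly these or the ribosomal protein genes were transcribed. No biological explanation was tested.

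The low number of peaks on chromosome 4 is consistent with few regions being called there at all. Pooled regions below the threshold were also rare on it (73 of 24988, 0.292%, against 0.737% expected, exact binomial p = 1.71e-20), and the odds ratio of thresholded peaks against them was 0.682 (Fisher's exact p = 0.303). Why few regions were called there was not tested, and no biological explanation was tested.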
